A study of Mus musculus with 8 samples.

How the data were processed

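The series measured gene expression in immature bone-marrow-derived mouse dendritic cells after 1 day with a vaccine or as a negative control, with 1 library for each of 8 groups. Per the labels' protocols, RNA was taken up in TRIzol and sequenced by a company with an ultra-low-input kit, polyA selection and 150-bp paired-end Illumina reads. The authors deposited raw read counts per gene, 1 table per library with 49315 genes. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2, with the mouse build GRCm38. The annotation release, strand setting and treatment of reads with several positions are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be told apart. A kit for very little RNA amplifies the material, and PCR copies are counted as separate reads, so intervals and floors cover counting error only.

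Gene symbols and GRCm38 coordinates were taken through gene IDs: 49056 IDs matched GENCODE M21, 44858 of them with the same start and end. Genes without a symbol held 0.0053% of the counts. Total counts ran from 16836579 to 23207877 per library, and a floor of 3 counts corresponds to 0.129 to 0.183 CPM.

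Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), from 0.924 to 1.07, and turned into log2 CPM with a prior count of 0.5. Genes with a mean CPM of at least 1 over the 8 libraries were tested, 11990 in all. With 1 library per group no model was fitted and no p-value is given. A gene was called apart when its log2 ratio was 1 or more in size. Ratios between a pair of libraries carry exact conditional binomial 95% intervals, and ratios to the mean of the other three numbered libraries carry normal approximations. Against a library at 0 counts a fold is given as a lower bound from the floor of 3 counts per library. Comparisons were each of 7 vaccines against NC, CpG1- to CpG4-OVA-SQB against CpG0-OVA-SQB, each of these 4 against the mean of the others, and the 3 pairs among CpG2-OVA-SQB, CpG2-SQB + free OVA and free CpG + free OVA.

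The 33 gene lists, the rule for named genes and the comparisons were fixed before the data were examined. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression (20 bins), and called apart at or below the 2.5th or at or above the 97.5th percentile. In 34 cases a list held a gene at 0 counts in 1 library, and setting these genes to their bound moved none of the medians. Named genes had a symbol, coded for protein, were neither mitochondrial nor provisional models, had a mean CPM of at least 5, and had 100 counts or more in the higher library. The rule took the 10 highest and 10 lowest by the smallest ratio to NC over all 7 vaccines, and 5 each way for CpG0-OVA-SQB against NC. By the smallest ratio over CpG1- to CpG4-OVA-SQB against CpG0-OVA-SQB it took 10 each way, and 3 each way for each of these 4 against the others. It took 10 each way for CpG2-OVA-SQB against either free OVA group, 5 each way for the last pair, up to 4 members per list and comparison, and a panel of 12 immune genes. Of the genes taken by this rule, 2 are not reported here. Gbp7, Ighm, Cd79a, the lung genes outside the rule and the genes named for the mixing test were chosen after their values were seen.

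GC content and the GC of the richest 200-base window (steps of 20 bases) came from the longest GENCODE M21 transcript of each gene. Exon length was the one deposited with the counts. Alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a mean CPM of at least 5, a prior count of 5, protein-coding genes only, and calls by counting interval. Ratios corrected for GC and length with splines of 5 degrees of freedom, analyses without GC-rich genes, and counts without CpG2-SQB + free OVA or CpG2-OVA-SQB were added after the data were seen.

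The scripts were tested on simulated counts for CpG2-OVA-SQB against the free mixture over 11990 genes. With counting noise alone, 98.0% of genes set apart by a log2 of 1.5 and 100% of those set apart by 3 were called, with 0.09% of unchanged genes. With the spread of CpG1- to CpG4-OVA-SQB, which includes differences between vaccines, the values were 84.0%, 100% and 3.57%. Lists of unchanged genes were called in 3.5% and 7.0% of cases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, patsy 1.0.2 and matplotlib 3.10.9 were used.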

Results

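Polyadenylated RNA was sequenced as 150-bp pairs from immature mouse dendritic cells, grown from bone marrow and given a vaccine for 1 day. The series asks how the arrangement of CpG on DNA origami bears on cancer vaccination. CpG DNA is a ligand of the endosomal receptor Tlr9, and OVA is the usual short name of ovalbumin, a model antigen. Of the 8 groups, 5 received OVA-SQB preparations named CpG0, CpG1, CpG2, CpG3 and CpG4. Another group received free CpG with free OVA, 1 received CpG2-SQB with free OVA, and 1 was the negative control (NC). The labels spell out neither the digits nor SQB, so these are used here as names without an order. Each group had 1 library, so there was no replicate check and no test between conditions. Intervals are 95% intervals that cover counting error only, and list percentiles describe these libraries only.

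The libraries held 16836579 (CpG3-OVA-SQB) to 23207877 counts (CpG2-OVA-SQB), with 17911 to 18978 genes detected. Of these, 11990 genes passed the expression filter. A gene or list median is given as a log2 ratio or a fold, and a gene is called apart when it differed at least 2-fold. The libraries differed in the level of GC-rich genes. These are genes whose richest 200-base window holds more than 74% GC, and they made up 18.9% of the tested genes. In the richest decile the median log2 deviation from the mean of all libraries was 0.50, 0.56 and 0.52 in CpG1-, CpG3- and CpG4-OVA-SQB. It was -0.08 in CpG0-OVA-SQB, -0.18 in CpG2-OVA-SQB, -0.18 in the free mixture, -0.74 in CpG2-SQB + free OVA and -0.41 in NC. Log2 ratios between libraries also followed exon length. The Spearman correlation was 0.457 for CpG2-OVA-SQB against CpG2-SQB + free OVA and 0.242 for CpG2-OVA-SQB against the free mixture. It was 0.177 to 0.241 for CpG1- to CpG4-OVA-SQB against CpG0-OVA-SQB. Random lists were matched on expression, not on length or GC. Lung surfactant transcripts were present in every library, with Sftpc at 32.0 CPM in CpG2-OVA-SQB, 46.0 CPM in NC and 93.0 to 225 CPM in the other 6. Mitochondrial genes held 0.217% of the counts in NC, 0.348% with the free mixture (the lowest vaccine) and 0.643% in CpG0-OVA-SQB (the highest).

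**Figure D1:**
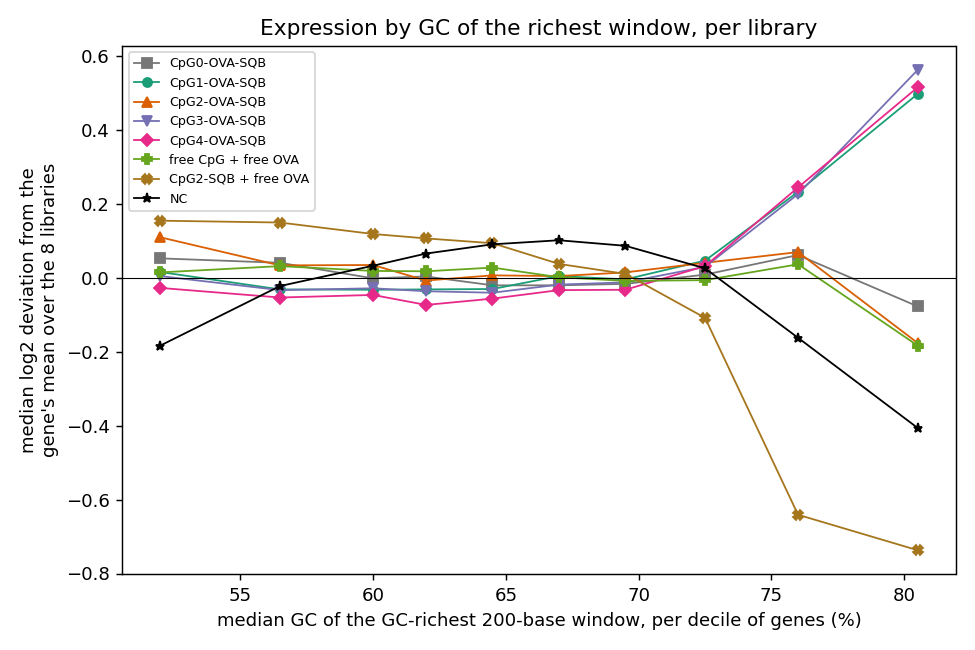
Median log2 deviation of each library from the gene's mean over the 8 libraries (vertical axis), by decile of genes ranked on GC of the richest 200-base window (horizontal axis, percent); each line is 1 library. The lines lie close to 0 in the middle deciles and spread from -0.74 to 0.56 in the richest.

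The first comparison set each vaccine against NC. Interferon-induced genes, chemokines and inflammatory cytokines were higher in all 7 vaccine libraries, and MHC class II, cell-cycle and cholesterol synthesis genes were lower. The type I interferon response list had 41 tested genes, of which 40 were at least 2-fold higher in CpG0-OVA-SQB (Gbp7 was the exception) and 41 in each of the other 6 vaccines. Its median log2 ratio was 2.76 in CpG0-OVA-SQB, 4.42, 4.30, 4.22 and 4.50 in CpG1- to CpG4-OVA-SQB, 4.13 with the free mixture and 4.26 with CpG2-SQB + free OVA. Among its members, Irf7, a transcription factor of the interferon response, was 28.0- to 145-fold higher. The antiviral gene Rsad2 was 29.3- to 215-fold higher, and Isg15, a ubiquitin-like modifier, 19.2- to 66.2-fold higher. The type I interferon genes themselves were near the floor: none of 20 passed the filter, and Ifnb1 had 0 counts in NC, 2 in CpG0-OVA-SQB, 2 with the free mixture and 17 in CpG4-OVA-SQB.

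Genes were ranked by the smallest ratio over the 7 vaccines, with the prior count added. The genes furthest above NC were Enpp2, Ifi213, Dcn, Cxcl5, Ifi206, Ifi44, Ifi205, Oasl1, Ly6i and Cxcl10. The ranks of Enpp2, Ifi213 and Dcn rest on the prior count, since these genes had 0 counts in NC. Their smallest lower bounds, given below, lie under the smallest ratio of Cxcl5, so their order is not settled. The bound of Dcn also lies under the ratio of Cxcl10, so its place among these genes is not settled either. Enpp2 encodes autotaxin, a secreted enzyme that makes lysophosphatidic acid, and lies on chromosome 15 from 54838898 to 54920146 (GRCm38). It had 0 counts in NC and was at least 86.1-fold higher in CpG0-OVA-SQB and at least 559-fold in CpG2-OVA-SQB. Dcn, which encodes the matrix proteoglycan decorin (chromosome 10, 97479500 to 97518162), also had 0 counts in NC and reached at least 38.1- to 532-fold. Ifi213, Ifi206 and Ifi205 are neighbouring members of one interferon-inducible family, so reads may be split between them. Ifi213 was at least 72.7- to 359-fold higher, Ifi206 99.1- to 438-fold and Ifi205 80.6- to 388-fold. Cxcl5, a neutrophil-attracting chemokine, was 103- to 540-fold higher and the interferon-induced Oasl1 62.5- to 417-fold. The T-cell-attracting chemokine Cxcl10 had 1 count in NC, so its ratio was loosely bounded: 54.9 in CpG0-OVA-SQB (interval 14.2 to 3259) and 265 in CpG1-OVA-SQB (70.5 to 15610).

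At the other end lay Fbp1, Asgr2, Fcrls, Gfra2, Selenbp1, Mgl2, Aqp3, Ciita, Cldn1 and Hebp2. The gluconeogenic enzyme gene Fbp1 (chromosome 13, 62864753 to 62888282) stood at 61.6 CPM in NC and at 0.798 CPM or less in every vaccine. The C-type lectin gene Mgl2 was 5.48- to 36.5-fold lower, the Fc receptor-like gene Fcrls 9.40- to 86.1-fold, and the water channel gene Aqp3 5.29- to 131-fold. Ciita, the master regulator of MHC class II transcription, was 5.27- to 13.8-fold lower. In the MHC class II list 9 of 15 genes were at least 2-fold lower in every vaccine, with medians from -1.27 (CpG0-OVA-SQB) to -2.20 (CpG4-OVA-SQB). H2-Ab1, a class II beta chain gene, stood at 4589 CPM in NC and at 815.5 to 1286 CPM in the vaccines. MHC class I genes lay the other way, with medians from 0.79 to 1.40. The class I gene H2-Q6 stood at 13.5 CPM in NC and 112 to 552 CPM in the vaccines, although reads of the H2-Q family may be shared between copies.

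Dendritic cell maturation genes had medians of 0.83 in CpG0-OVA-SQB, 1.61, 1.66, 1.53 and 1.38 in CpG1- to CpG4-OVA-SQB, 0.96 with the free mixture and 1.40 with CpG2-SQB + free OVA. In the panel of genes fixed in advance, the costimulatory gene Cd86 was 4.41- to 8.01-fold higher than in NC. Cd40 was 2.68- to 7.12-fold higher, the lymph node homing receptor gene Ccr7 3.68- to 5.67-fold, and Cd80 1.43- to 2.61-fold. Among the cytokines, Il12b was 3.87- to 8.15-fold higher, Il1b 6.82- to 21-fold and Tnf 1.77- to 3.27-fold. Il6 was 145-fold higher in CpG1-OVA-SQB, where it was furthest above NC. Tlr9 had at most 8 counts in any library and is given no fold. Inflammatory cytokines as a list had medians of 1.44 (CpG0-OVA-SQB) to 2.83 (CpG1-OVA-SQB), and Th1-associated genes 1.24 to 2.76. Chemokine medians ran from 1.77 to 2.46. Beside Cxcl5 and Cxcl10, the neutrophil-attracting Cxcl3 was 50.8-fold higher in CpG0-OVA-SQB and 134-fold in CpG1-OVA-SQB, and the T-cell-attracting Ccl5 11.8- and 41.7-fold. Ccl17, a chemokine for Ccr4-bearing T cells, ran against its list at 8773 CPM in NC and 1338 to 6674 CPM in the vaccines. The lists of NF-kB targets (0.79 to 1.26) and of cytosolic DNA sensing genes (0.44 to 0.71) were also higher, the latter not beyond random lists in CpG4-OVA-SQB (0.45).

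**Figure D2:**
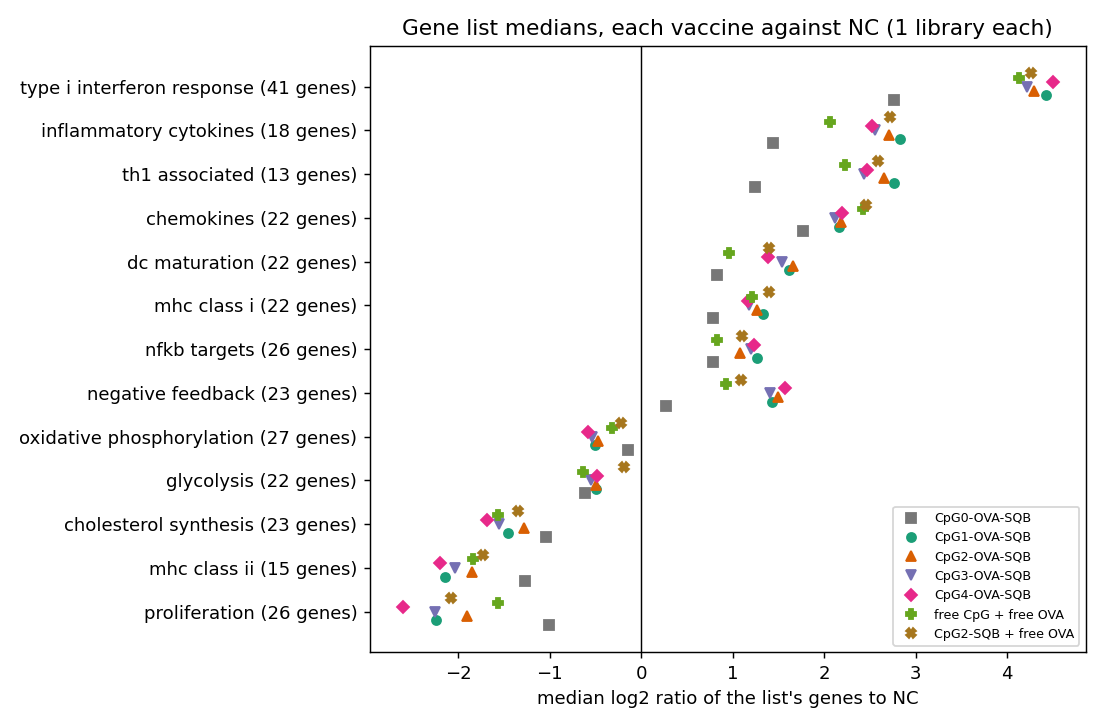
Median log2 ratio to NC of the tested genes in 13 of the 33 lists fixed in advance (horizontal axis), with 1 symbol per vaccine library and the number of tested genes beside each list. The interferon response list lies between 2.76 and 4.50, with CpG0-OVA-SQB lowest, and the proliferation list between -2.61 and -1.01.

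Proliferation genes had medians of -1.01 in CpG0-OVA-SQB and -1.57 to -2.61 in the other 6 vaccines, with 14 of 26 genes at least 2-fold lower in CpG0-OVA-SQB and 23 or 24 in the others. Birc5, which encodes survivin, was 2.63- to 9.38-fold lower. Cholesterol synthesis genes had medians of -1.04 to -1.69, and Sqle, which encodes squalene epoxidase, was 3.92- to 6.86-fold lower. Glycolysis genes had medians of -0.19 to -0.64, beyond random lists in all 7 vaccines. Oxidative phosphorylation genes were at -0.15 in CpG0-OVA-SQB, inside the range of random lists, and at -0.23 to -0.58 in the other 6. Negative feedback genes were at 0.27 in CpG0-OVA-SQB, also inside that range, and at 0.92 to 1.58 in the other 6. The immunometabolic enzyme gene Acod1 of that list was 4.94- to 10.6-fold higher. Th2-associated genes were lower than random lists in CpG3-OVA-SQB (-0.44), CpG4-OVA-SQB (-0.49), the free mixture (-1.09) and CpG2-SQB + free OVA (-0.49), and inside their range in the others (-0.10 to -0.27). Genes of antigen uptake in immature cells were lower than random lists in CpG0-OVA-SQB (-0.43) and inside their range in the other 6 (-0.20 to 0.25). No vaccine had a median beyond random lists for the Tlr9 pathway (at most 0.42), p53 and apoptosis (-0.15 to 0.20), endoplasmic reticulum stress (-0.03 to 0.18) or dissociation stress (-0.01 to 0.31).

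Markers of other cells differed from NC as well. The B-cell list was higher in all 7, with medians of 1.68 to 2.15 in 6 vaccines and 3.38 with the free mixture. Mast cell and basophil markers had medians of 0.65 to 1.24. The stromal list, with 6 tested genes that include Dcn, had medians of 0.81 to 1.57 and lay inside the range of random lists in CpG4-OVA-SQB (1.10). With a mean CPM of at least 5 its CpG0-OVA-SQB median was -0.47 in place of 0.81. T and NK cell markers (5 genes) had medians of 1.01 to 1.72, beyond random lists in CpG0- and CpG2-OVA-SQB, the free mixture and CpG2-SQB + free OVA.

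In numbers, 1269 genes were at least 2-fold higher and 610 lower in CpG0-OVA-SQB than in NC. For CpG1- to CpG4-OVA-SQB the counts were 2241 and 1160, 1686 and 1197, 2306 and 1175, and 2306 and 1254. With the free mixture they were 1535 and 909. With CpG2-SQB + free OVA they were 1332 and 1778, so 42.8% were higher, against 31.4% when libraries were scaled by total counts, 47.2% after a correction for GC and length and 50.4% without GC-rich genes. GC-rich genes made up 20.6% to 29.7% of the genes apart from NC. Genes higher in all 7 vaccines numbered 599 and genes lower in all 7 numbered 327. Unchanged libraries were simulated for all 8 groups, the shared control included, from the mean over the libraries with the spread of CpG1- to CpG4-OVA-SQB. They gave means of 9.95 and 0.56 (maxima 21 and 4), and independent lists of these sizes would share 0.02 and 0.00. That spread leaves out NC and the other vaccines, so the simulated numbers may be too low. With a single control library, part of the excess may come from NC itself. Without CpG2-SQB + free OVA, the library lowest in GC-rich genes, 766 and 336 genes were shared.

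The CpG0-OVA-SQB library was also ranked against NC on its own. With the prior count, the genes furthest above NC were Enpp2, Ifi213 and Dcn, which had no counts in NC. The next genes were Cxcl5 (103-fold, interval 55.5 to 255) and Ifi206 (99.1-fold, 51.2 to 265). The lower bounds of the former genes, 86.1-fold for Enpp2 and less for the others, lie under both ratios. Their order relative to Cxcl5 and Ifi206 is therefore not settled. The genes furthest below were Fbp1 (83.6-fold, 52.3 to 155), Asgr2 (11.0-fold, 9.54 to 12.8), Fcrls (9.40-fold, 8.71 to 10.2), Selenbp1 (9.19-fold, 7.78 to 11.0) and the mannose receptor gene Mrc1 (8.64-fold, 7.66 to 9.80). Cd86 was 4.41-fold higher (4.13 to 4.72) and Il1b 6.82-fold higher (6.38 to 7.32).

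**Figure D3:**
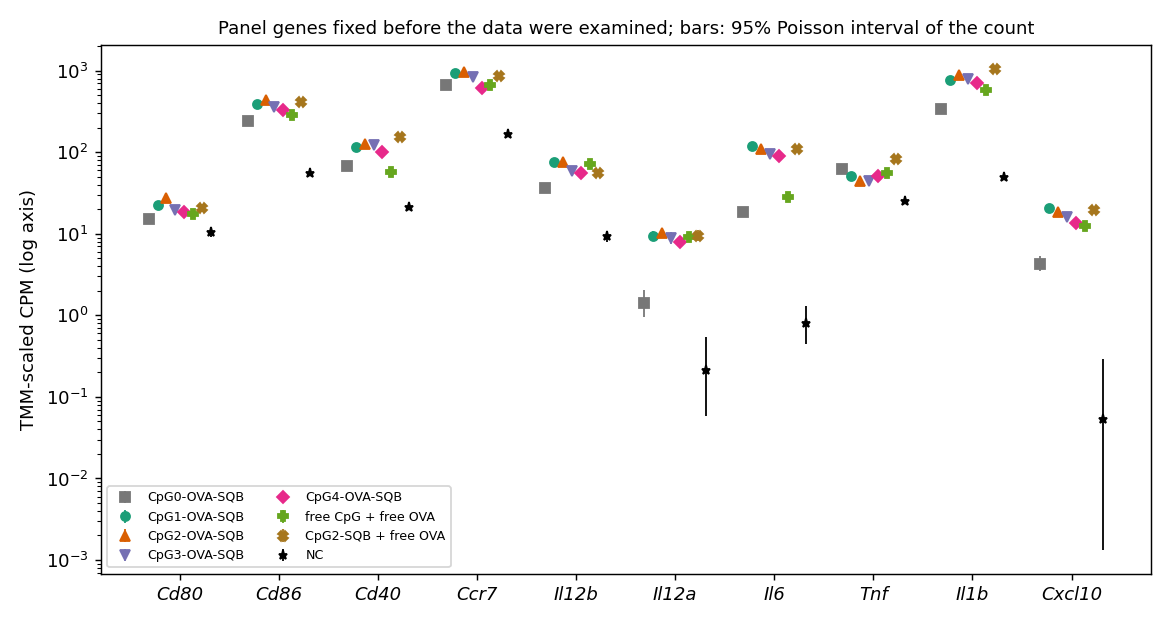
Expression (CPM after TMM scaling, log axis) of 10 panel genes in each of the 8 libraries; each symbol is 1 library and bars are 95% Poisson intervals of the count. Il6 stands at 0.795 CPM in NC, 28.6 CPM with the free mixture and 89.4 to 119 CPM in CpG1- to CpG4-OVA-SQB.

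CpG1- to CpG4-OVA-SQB were next compared with CpG0-OVA-SQB. The interferon response list was higher in all 4, with median log2 ratios of 1.27, 1.32, 1.20 and 1.36. Inflammatory cytokines (0.85 to 1.23), Th1-associated genes (0.83 to 1.41), chemokines (0.72 to 0.84), negative feedback (0.77 to 0.85), maturation (0.38 to 0.66), MHC class I (0.45 to 0.53) and NF-kB targets (0.36 to 0.57) were higher too. Proliferation (-0.93 to -1.55), MHC class II (-0.38 to -0.51), oxidative phosphorylation (-0.39 to -0.47) and cholesterol synthesis (-0.33 to -0.43) were lower. Macrophage markers were higher in CpG2- (0.35), CpG3- (0.45) and CpG4-OVA-SQB (0.50), mast cell and basophil markers in CpG2-OVA-SQB (0.62), and glycolysis genes in CpG1- (0.28) and CpG4-OVA-SQB (0.27). Neutrophil markers were lower in CpG1- (-0.29), CpG3- (-0.57) and CpG4-OVA-SQB (-0.38), eosinophil markers in CpG3- (-0.66) and CpG4-OVA-SQB (-0.54), plasmacytoid markers in CpG3-OVA-SQB (-0.46), and B-cell (-0.60) and Th2-associated (-0.28) genes in CpG4-OVA-SQB. The Tlr9 pathway list was higher than random lists in all 4 (0.33 to 0.43), although it stood inside their range against NC.

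Genes furthest above CpG0-OVA-SQB in all 4 were Ifit1bl1, Mmp10, Gja1, Ptgs2, Dcn, Cxcl1, Ms4a4c, Lox, Saa3 and Csf3. The interferon-induced Ifit1bl1 (chromosome 19, 34592888 to 34601968) was 21.9- to 26.6-fold higher; it belongs to a multigene family whose members may share reads. Mmp10, a matrix metalloproteinase gene, was 18.1- to 27.7-fold higher, and Ptgs2, which encodes the inducible cyclooxygenase, 12.1- to 13.5-fold. The neutrophil chemokine gene Cxcl1 was 10.7- to 13.4-fold higher, the acute-phase gene Saa3 9.15- to 11.0-fold and the granulocyte growth factor gene Csf3 8.40- to 13.1-fold. Gja1 (13.5- to 14.5-fold), Dcn (11.6- to 13.0-fold) and Lox (up to 14.8-fold), which encode a gap junction protein, decorin and a collagen-crosslinking enzyme, are typical of stromal cells; the stromal list stood 0.61 to 0.78 above CpG0-OVA-SQB, beyond random lists for CpG1- and CpG2-OVA-SQB. Il6 was 4.89- to 6.51-fold higher, Il12a 5.52- to 7.10-fold and Cd86 1.34- to 1.82-fold, whereas Tnf was 1.24- to 1.42-fold lower. Genes furthest below were Aqp3, Hebp2, Anxa8, Fcrls, Mgl2, Tnc, Asgr2, Ak1, Smim5 and Rufy4. Aqp3 was 8.22- to 14.7-fold lower, Hebp2 8.11- to 12.2-fold, the annexin gene Anxa8 6.36- to 8.49-fold and Mgl2 5.36- to 6.67-fold. Tnc, which encodes tenascin C, was 4.87- to 5.42-fold lower than in CpG0-OVA-SQB, where it stood at 18.6 CPM against 6.95 CPM in NC.

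The counts of genes higher and lower than in CpG0-OVA-SQB were 989 and 442 for CpG1-, 587 and 605 for CpG2-, 1083 and 466 for CpG3-, and 1135 and 609 for CpG4-OVA-SQB. All 4 shared 364 higher and 168 lower genes. The shares of higher genes were 69.1%, 49.2%, 69.9% and 65.1%. They were 59.2%, 39.7%, 58.1% and 53.8% with libraries scaled by total counts, and 58.7%, 57.3%, 58.0% and 54.4% without GC-rich genes, so the balance of CpG2-OVA-SQB changed side with the setting. GC-rich genes made up 31.0%, 22.5%, 34.1% and 29.3% of the genes apart.

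Within CpG1- to CpG4-OVA-SQB, each library was compared with the mean of the other three. Proliferation genes were higher in CpG2-OVA-SQB (median 0.34) and lower in CpG4-OVA-SQB (-0.43). In CpG4-OVA-SQB the mitotic genes Ercc6l, Nek2 and Kif20b were 2.84-fold (interval 1.85 to 4.33), 2.45-fold (1.73 to 3.46) and 2.42-fold (1.54 to 3.78) lower. In CpG2-OVA-SQB, Kif20b was 2.46-fold higher (1.88 to 3.22) and Frmd4b 2.04-fold (1.59 to 2.62). Interferon response medians ran from -0.11 in CpG3-OVA-SQB to 0.11 in CpG2-OVA-SQB. The maturation list stood at 0.20 in CpG2- and -0.22 in CpG4-OVA-SQB. Inflammatory cytokines (-0.14) and Th1-associated genes (-0.19) were also lower than random lists in CpG4-OVA-SQB. Plasmacytoid markers were at 0.48 in CpG1- and -0.45 in CpG3-OVA-SQB, mast cell and basophil markers at 0.35 in CpG2- and -0.39 in CpG3-OVA-SQB, and eosinophil markers at 0.22, 0.32, -0.40 and -0.18 in CpG1- to CpG4-OVA-SQB. Neutrophil markers were at 0.31 in CpG2- and -0.19 in CpG3-OVA-SQB, where the neutrophil gene Ly6g stood at 10.3 CPM against 16.7 to 22.9 CPM in the others.

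The remaining named genes of this comparison were mostly GC-rich. Jund, a subunit of the AP-1 transcription factor (chromosome 8, 70698949 to 70700616), stood at 2.11 CPM in CpG2-OVA-SQB and at 54.9, 165 and 101 CPM in CpG1-, CpG3- and CpG4-OVA-SQB, and its richest window holds 82.0% GC. Tmem160 and Habp4 were 19.1-fold (14.8 to 24.7) and 17.7-fold (11.1 to 28.6) lower in CpG2-OVA-SQB. Dapk3, a kinase gene, and Arf6, a small GTPase gene, were 11.0-fold (8.91 to 13.7) and 6.47-fold (6.16 to 6.81) higher in CpG3-OVA-SQB. Habp4, Bloc1s3 and Slc25a33 were 2.91-, 2.75- and 2.66-fold higher in CpG1-OVA-SQB, and Pccb, Thnsl1 and Fbxl2 were 2.38-, 2.25- and 1.85-fold lower. Tysnd1 was 2.72-fold higher in CpG4-OVA-SQB, and Lrrc45 and Zfp748 were 2.31- and 2.01-fold lower in CpG3-OVA-SQB. Genes apart numbered 153 for CpG1-, 742 for CpG2-, 376 for CpG3- and 261 for CpG4-OVA-SQB, of which 44.4%, 72.0%, 59.6% and 36.0% were GC-rich. Without the GC-rich genes the counts were 83, 206, 150 and 166. Shares of higher genes were 70.6%, 5.0%, 77.9% and 54.0%, and without the GC-rich genes 55.4%, 16.5%, 54.7% and 30.1%. For CpG4-OVA-SQB the share was 39.5% after a correction for GC and length and 83.1% with a mean CPM of at least 5, and for CpG2-OVA-SQB it was 44.3% without the expression filter.

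CpG2-OVA-SQB was then compared with free CpG + free OVA. These groups differ in whether CpG and OVA were on the SQB. The label of the free mixture names no SQB, so presence of the SQB cannot be told apart from attachment to it. Interferon response, inflammatory cytokine and maturation genes were higher in CpG2-OVA-SQB, with medians of 0.33, 0.63 and 0.66. Nos2, the inducible nitric oxide synthase gene (chromosome 11, 78920787 to 78960254), was 10.2-fold higher (9.45 to 11.1) and stood at 30.5 CPM with the free mixture, 36.8 CPM in CpG0-OVA-SQB and 313 CPM in CpG2-OVA-SQB. Cyp1b1, a cytochrome P450 gene, was 23.7-fold higher (13.7 to 50.2), the iron hormone gene Hamp 9.52-fold (7.16 to 13.2), Ptgs2 7.56-fold (6.64 to 8.67) and the alarmin gene Il33 6.93-fold (6.44 to 7.48). Mt3 (8.85-fold), Kif1a (5.69-fold), Lmbr1 (5.35-fold), Shroom3 (5.31-fold) and Syt7 (4.97-fold) completed the higher genes. Not all of these genes were low in CpG0-OVA-SQB. Il33 stood at 198 CPM there against 36.7 CPM with the free mixture. Mt3 and Kif1a were 2.05- to 2.27-fold and 1.33- to 1.58-fold higher there than in CpG1- to CpG4-OVA-SQB. Nos2, Cyp1b1, Hamp and Ptgs2 went the other way, 3.21- to 13.5-fold higher in CpG1- to CpG4-OVA-SQB than in CpG0-OVA-SQB. Lmbr1 and Shroom3 were 1.23- to 1.72-fold higher, and Syt7 lay on both sides. Of the lower genes, the macrophage gene Mrc1 (6.56-fold, 5.71 to 7.60) and the Fc receptor-like gene Fcrls (7.81-fold, 6.28 to 9.94) go with a macrophage marker list at -0.68. Habp4, Zfp771, Tmem160, Bloc1s4, Srm and Rab24 were 6.38- to 8.82-fold lower and are GC-rich, and Sftpc was 6.39-fold lower (5.92 to 6.93).

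B-cell markers (-1.34), plasmacytoid dendritic cell markers (-0.81), neutrophil markers (-0.52) and type 2 dendritic cell markers (-0.49) were lower in CpG2-OVA-SQB than with the free mixture. So were proliferation (-0.47), antigen uptake (-0.42), MHC class II (-0.40) and oxidative phosphorylation (-0.15) genes, while Th1-associated genes (0.53), negative feedback (0.32), glycolysis (0.24) and NF-kB targets (0.22) were higher. In all, 345 genes were higher and 462 lower. Together these were 807 of 11990 tested genes. In the simulation of this pair with the spread of CpG1- to CpG4-OVA-SQB, 3.57% of unchanged genes were called. A large part of the 807 may therefore be noise, although that spread includes differences between vaccines.

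CpG2-OVA-SQB and CpG2-SQB + free OVA differ in whether OVA was on the SQB. Of 32 lists with a tested gene, 3 lay beyond random lists (6 at a mean CPM of at least 5): the interferon response (median 0.15) and negative feedback (0.16) lists were higher in CpG2-OVA-SQB and oxidative phosphorylation lower (-0.30). Cytokines (-0.08), maturation (0.12) and MHC class II (-0.25) lay inside their range. In the simulations of CpG2-OVA-SQB against the free mixture, 3.5% and 7.0% of lists of unchanged genes were called. Some of the 3 lists may therefore be noise. Single genes were far apart, 1210 higher and 133 lower in CpG2-OVA-SQB, and 49.8% of them were GC-rich. Socs1, a feedback inhibitor of cytokine signalling (chromosome 16, 10783808 to 10785536; richest window 75% GC), stood at 4.90 CPM in CpG2-SQB + free OVA, 70.1 CPM in CpG2-OVA-SQB and 71.0 CPM in NC, a 14.2-fold difference (11.5 to 18.1) between the former pair. Scand1 was 26.2-fold higher (16.0 to 49.8), Fance, a Fanconi anaemia gene, 17.3-fold (8.32 to 51.2), Klrg2 14.4-fold (7.23 to 38.6), Fam89a 13.7-fold (7.10 to 33.8) and the mitochondrial gene C1qbp 13.0-fold (10.3 to 16.8). Crtap, Abhd17a, Zfp622 and the small GTPase gene Rala were 11.1- to 11.7-fold higher, and all 10 of these genes are GC-rich. The lower genes were led by lung transcripts: Cxcl15 (6.95-fold, 4.84 to 10.6), Sftpd (5.99-fold, 3.96 to 9.74), Cbr2 (5.79-fold, 4.12 to 8.55), Sftpc (5.70-fold, 5.26 to 6.19) and Sftpa1 (4.91-fold, 4.31 to 5.61). U2af1l4, Setd4, Leng9, Cfap45 and Mettl27 were 2.02- to 2.26-fold lower. After a correction for GC and length that was chosen after the data had been seen, 898 genes were apart and 80.4% of them were higher.

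Last, CpG2-SQB + free OVA was compared with the free mixture. These groups differ in whether CpG was on the SQB and, by the labels, in whether an SQB was present. These differences cannot be told apart here. Cytokines (0.59), chemokines (0.54), maturation (0.45), glycolysis (0.36), endoplasmic reticulum stress (0.34), Th1-associated genes (0.32), NF-kB targets (0.25) and interferon response genes (0.18) were higher. Mt3, a metallothionein gene, was 15.6-fold higher (9.25 to 31.2), Hamp 14.9-fold (11.3 to 20.6), Il33 8.00-fold (7.42 to 8.64), Kif1a 7.95-fold (7.14 to 8.90) and Nos2 7.92-fold (7.30 to 8.63). Mt3 was 1.03- to 20.4-fold lower than NC over the 7 vaccines. Il33 stood at 36.7 CPM with the free mixture, 65.8 CPM in NC and 198 CPM in CpG0-OVA-SQB. Mt3 and Kif1a were higher in CpG0-OVA-SQB than in CpG1- to CpG4-OVA-SQB, whereas Hamp and Nos2 were lower there. Lower were Scand1 (50.3-fold, 30.8 to 95.2), Zfp771 (3 counts, ratio 46.9, 18.1 to 262), Cebpd (43.8-fold, 26.8 to 82.9), Socs1 (36.6-fold, 29.6 to 46.5) and Rab5if (34.1-fold, 26.6 to 45.1), all GC-rich. B-cell (-1.55), plasmacytoid (-0.84), macrophage (-0.82), type 2 dendritic cell (-0.60) and neutrophil (-0.29) markers were lower, as were proliferation (-0.48) and antigen uptake (-0.42) genes. In all, 330 genes were higher and 1252 lower, and 46.6% of them were GC-rich; without the GC-rich genes 840 were apart. The share of higher genes was 20.9%, against 14.1% with libraries scaled by total counts, 35.6% without GC-rich genes and 36.8% without the expression filter.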

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

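Of the tests in this part, the thinning test had its criterion set before its result was seen, and the other 4 were chosen or given their criteria after related values had been seen. No group had enough libraries to look for a library far from its group.

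Among 121 tested genes named in the text, 20 were at least 2-fold higher than NC in 1 vaccine and at least 2-fold lower in another, a difference that was not tested. The values here are differences between the log2 ratios to NC of the highest and the lowest vaccine. For 15 of the 20 the lowest was CpG2-SQB + free OVA. The 121 genes include those named for their rank against that library. This count and the share of GC-rich genes therefore follow in part from the selection. Against CpG4-OVA-SQB the difference was 6.26 for Tmem160, 4.84 for Rab24, 4.61 for Rala and 4.59 for Tysnd1. Against CpG3-OVA-SQB it was 6.86 for Jund, 5.56 for Rab5if and 4.08 for Zfp622. Against CpG1-OVA-SQB it was 5.71 for Zfp771, 5.19 for Bloc1s3, 4.70 for Klrg2 and 4.36 for Bloc1s4. Against the free mixture it was 5.45 for Cebpd and 5.20 for Socs1, and against CpG0-OVA-SQB 4.19 for Abhd17a and 2.75 for Nes. With the free mixture lowest, Dapk3 differed by 5.6 from CpG3-OVA-SQB, Tnc by 4.87 and Kif1a by 3.16 from CpG0-OVA-SQB. With CpG0-OVA-SQB lowest, C1qa differed by 3.54 and C1qb by 2.52 from the free mixture. All but Tnc, Kif1a, C1qa and C1qb are GC-rich.

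A second pattern is the gap between CpG2-OVA-SQB and CpG2-SQB + free OVA, 1343 genes. Thinning the deeper library left a mean of 1361 genes apart (1341 to 1377 over 20 draws). The library size was scaled down with the counts, so thinning left the expected ratios unchanged and mainly added noise. The number apart could hardly fall, and no conclusion on depth is drawn. Over the tested genes, the log2 ratio of this pair had a Spearman correlation of 0.457 with exon length and 0.315 with GC of the richest window. The gap thus follows length as well as GC. Loss of GC-rich transcripts in 1 library is a candidate explanation for the 669 GC-rich genes apart: such genes were apart 4.26 times as often as other genes (29.5% against 6.9%). It cannot be told apart from other causes for the pattern as a whole: 49.8% of the genes were GC-rich, past the bound of 40% set for this cause, but 56.2% stayed apart after the correction for GC and length, above the share of less than 50% that this cause was to leave. Nor can it for the 674 genes that are not GC-rich, of which 62.3% stayed apart, between the bounds of 25% and 75%. Giving OVA free, the biological difference named by the design, stays open too. The genes lower in CpG2-SQB + free OVA had a median log2 ratio of -0.14 (quartiles -0.47 and 0.29) between the free mixture and CpG2-OVA-SQB. That mixture also differs in its CpG, and its label names no SQB.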

How the results depend on the processing

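The corrections for GC and length, the analyses without GC-rich genes and those without single libraries were chosen after the data were seen. Over all alternatives, 4430 of 4608 list medians kept their call against the percentile limits, 99 moved beyond a limit, 77 moved inside, and 2 reversed. DESeq2 size factors and total counts shift all ratios of a comparison nearly alike, random lists included. They could hardly move a call, and under each of them all 576 medians kept theirs, so these agreements say little. A change of sign inside the limits was not counted. Each move of a named gene's ratio was set against the mean distance from the ratio to the ends of its counting interval. Of 1432 ratios under the 4 settings that can move a ratio, 1350 moved by less than this distance. The other 82 moved further, with total counts (33) or after the correction for GC and length (49). Counts of genes apart stayed within 1.5 times of the reported value in 124 of 165 cases. DESeq2 size factors, total counts, protein-coding genes only and calls by counting interval moved no count by more, but total counts shifted the median of all genes by -0.21 to 0.11 between libraries, and differences are relative to that.

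Dropping the filter adds genes with few counts. Genes apart from NC then numbered 7268, 9264, 8564, 9330 and 9371 for CpG0- to CpG4-OVA-SQB, 8245 for the free mixture and 8576 for CpG2-SQB + free OVA. Against CpG0-OVA-SQB there were 7106, 6655, 7236 and 7325, and against the mean of the others 4530, 5090, 4935 and 4746. The delivery pairs had 6329 (CpG2-OVA-SQB against the free mixture), 6677 (against CpG2-SQB + free OVA) and 6980, and all 7 vaccines shared 982 higher and 943 lower genes. The shares of higher genes were 54.8%, 50.2%, 55.6% and 53.8% against CpG0-OVA-SQB, 55.8%, 44.3%, 58.6% and 53.5% against the mean of the others, and 63.2% between CpG2-OVA-SQB and CpG2-SQB + free OVA. The stromal list of CpG2-SQB + free OVA against the free mixture reversed from 0.59 to -0.23, with more members tested.

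With a mean CPM of at least 5, fewer genes were tested. Genes apart from NC numbered 1181 for CpG0-OVA-SQB, 1570 for the free mixture and 2072 for CpG2-SQB + free OVA. Against CpG0-OVA-SQB there were 832, 671, 913 and 1045, against the mean of the others 39, 490, 171 and 65, and for the delivery pairs 411, 878 and 994. Shares of higher genes against the mean of the others were 92.3%, 0.4%, 98.2% and 83.1%. Shared genes numbered 395 and 213, the stromal list of CpG0-OVA-SQB against NC reversed from 0.81 to -0.47, and 6 lists in place of 3 lay apart between CpG2-OVA-SQB and CpG2-SQB + free OVA.

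A prior count of 5, which pulls in ratios of low counts, left 95 genes apart for CpG1-OVA-SQB and 167 for CpG4-OVA-SQB against the mean of the others. After the correction for GC and length, 5 lists lay apart between CpG2-OVA-SQB and CpG2-SQB + free OVA, where 898 genes were apart, and CpG4-OVA-SQB had 39.5% in place of 54.0% higher genes against the mean of the others; the cause was not tested. Without GC-rich genes, 1018 genes were apart between CpG3- and CpG0-OVA-SQB, 83, 206, 150 and 166 against the mean of the others, 672 between CpG2-OVA-SQB and CpG2-SQB + free OVA, and 840 between the latter and the free mixture. Without CpG2-OVA-SQB, the counts against the mean of the others were 156, 253 and 197 for CpG1-, CpG3- and CpG4-OVA-SQB. Depth limits the genes near the floor, among them the type I interferon genes and Tlr9.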

Other observations

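In this part, the test of sequence bias on the interferon list had its criterion set before its result was seen. The other tests, the comparison of the free mixture's lists and the lung markers summed were chosen after related values had been seen.

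The library of free CpG + free OVA stood apart in its macrophage and B-cell genes. Its macrophage list lay 1.09 above NC, against 0.00 to 0.41 in the other 6 vaccines, which were inside the range of random lists. The complement genes C1qa, C1qb and C1qc stood at 56.0, 439 and 266 CPM with the free mixture, and at no more than 15.6, 155 and 76.7 CPM in any other library. Mrc1 was at 64.8 CPM with the free mixture, 121 CPM in NC and 5.96 to 14.0 CPM in the other vaccines. The immunoglobulin genes Ighm and Igkc were at 217 and 144 CPM, against 25 and 1.70 CPM in NC and up to 69.4 and 51.7 CPM in the other vaccines, and Cd79a, a B-cell receptor gene, at 9.24 against 0.742 CPM in NC. None of the lists for type 1 (-0.07 to 0.36), type 2 (-0.09 to -0.41) or plasmacytoid (-0.40 to 0.62) dendritic cells, for eosinophils (-0.27 to 0.48) or for sex-linked genes (-0.05 to 0.33) lay beyond random lists against NC. Neutrophil markers did so in CpG3-OVA-SQB (-0.46), with -0.15 to 0.32 in the others. The erythroid list had 1 tested gene, Car2, at 1.46 to 1.97 above NC.

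The free mixture's interferon response median was 4.13 above NC, against 2.76 in CpG0-OVA-SQB and 4.22 to 4.50 in those 4. Its inflammatory cytokine median was 2.06, against 1.44 and 2.52 to 2.83. Its chemokine median was 2.42, against 1.77 and 2.12 to 2.19, but compared gene by gene the chemokines of CpG2-OVA-SQB had a median log2 ratio of 0.11 to the free mixture, inside the range of random lists. Differences between lists were not tested. Il6 stood at 28.6 CPM with the free mixture and 89.4 to 119 CPM in CpG1- to CpG4-OVA-SQB, and Cxcl1 at 15.3 against 69.4 to 86.4 CPM. Rsad2, of the interferon list, stood at 287 CPM against 495 to 599 CPM.

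Type I interferon response genes were higher in CpG0-OVA-SQB than in NC. The tables argue against sequence bias between the libraries, since the list median was 2.91 after the correction for GC and length and 2.76 before it. The first test of RNA of CpG1- to CpG4-OVA-SQB mixed into the CpG0-OVA-SQB library allowed fewer than 10 genes at least 2-fold above both NC and every one of those 4 libraries. Only 4 genes, Igkv8-19, Tnc, Nes and A730020M07Rik, lay there. A weaker response of the same kind would also lie between NC and those 4 libraries, so this test cannot tell it from mixing. A test added afterwards argues against 1 mixed share as the whole cause, since the shares implied by the 41 list genes had a 90th over 10th percentile of 3.7 (16.3% to 59.6%), beyond the bound of 3 set for it. Mixing on top of a response stays open, as does a response to the OVA-SQB preparation itself, which was not tested.

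Lung transcripts were present in these libraries of bone-marrow-derived cells. The sum of 10 lung-restricted markers was 51.4 CPM in CpG2-OVA-SQB, 70.6 CPM in NC and 152 to 320 CPM in the other 6 libraries, with the surfactant gene Sftpc the most abundant. The bound set against genes raised by every vaccine was a sum below NC in at least 1 vaccine by more than counting error. CpG2-OVA-SQB met this bound. As that rests on 1 library, the bound was not applied and no conclusion is drawn. A single source carried into every library cannot be told apart from several. The markers' counts departed from 1 common ratio with a chi-square over degrees of freedom of 8.7 (2.6 without Sftpb, Slc34a2 and Sftpc). The value of 8.7 was past the bound set against 1 source. That bound was not applied either, since the test sets single libraries against counting noise alone.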
